A study of Homo sapiens with 6 samples.

How the data were processed

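Gene expression was measured in U373, a human glioblastoma cell line, on 6 Affymetrix Human Genome U95 Av2 oligonucleotide arrays. Per the labels' protocols, total RNA was isolated with Tripure reagent, cleaned on RNeasy columns and turned into biotin-labelled cRNA by the manufacturer's procedure. Per the submitters' processing notes, the tool was MAS5, Affymetrix's algorithm that gives a single signal per probe set. Its version, a genome build and detection calls were not given in the sources used here, so no coordinates are given. The deposited values are MAS5 signal on a linear scale, and per array their mean, leaving out the lowest and highest 2% of probe sets, lies between 150.07 and 150.08, so the authors had scaled the arrays to a common level. No further scaling was applied for the reported values.

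The 6 samples form 6 groups of 1 array, taken from the labels. 1 group is untransfected, untreated cells at day 1. The other 5 are syk-transfected cells: untreated at day 1, ethanol-treated at day 1, treated with ethanol and ponasterone A at day 1, untreated at day 2, and treated with ethanol and ponasterone A at day 2. The labels give 10 µM for ponasterone A, called PonA here, which is a steroid that switches on genes placed under an ecdysone-inducible promoter. Per the series design text, such an ecdysone-inducible expression system was used. No condition was repeated on the same day, and nothing says whether cultures were independent, so the number of arrays limits the precision of every value.

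The table holds 67 control probe sets, which were used only for array quality, and 12558 others. Gene symbols came from the platform annotation given with the data, updated through Entrez identifiers to the symbols of a RefSeq gene table of assembly GRCh38.p14. A single symbol was given for 10943 probe sets, of which 10934 matched that table, and they stand for 8226 genes. Several symbols were given for 545 probe sets and none for 1070, and neither kind was named. Where a gene had several probe sets, the probe set with the highest mean signal over the 6 arrays stands for it.

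Signals under the 40th percentile of their array were set to that percentile, here called the floor, and then put on the log2 scale. The floor lay between 22.7 and 26.5 signal units. A fold from a value at the floor on 1 side is a lower bound. The PonA effect over both days was estimated with an additive limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with terms for PonA and for day over the 5 transfected arrays, 2 with PonA and 3 without. Probe sets above the floor on at least 2 of the 5 arrays were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 2 residual degrees of freedom, which hold the difference between ethanol-treated and untreated cells at day 1 and the difference between the PonA effects of the days, and eBayes added 4.48 prior degrees of freedom. The p-values therefore measure the PonA effect against those differences and not against repeated cultures. Where a probe set lies under the floor on both arrays of the ethanol comparison, that difference is only the one between their floors. SE denotes the moderated standard error of this fit. A fit with a PonA-by-day term over the same arrays, added after the results were seen, has 1 residual degree of freedom.

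Comparisons of 1 array with 1 array have no replicate check and no p-value. For them, probe sets above the floor on at least 1 side and at least 2-fold apart were counted. A stricter count took probe sets at least 2-fold apart the same way in 3 comparisons, PonA over ethanol at day 1, PonA over untreated at day 1 and PonA over untreated at day 2, the first and second of which share the PonA array of day 1.

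27 gene lists were fixed before the data were examined: SYK and ZAP70, the RXR genes, SYK signalling partners, immediate early and MAPK feedback genes, NF-kB and inflammatory genes, interferon-stimulated genes, mitosis, DNA replication, sterol synthesis, LXR and retinoid targets, unfolded protein and integrated stress response, heat shock, metallothionein and oxidative stress, hypoxia and glycolysis, p53 targets, matrix and adhesion, TGF-beta targets, apoptosis and survival, alcohol and aldehyde metabolism, ribosomal proteins, oxidative phosphorylation, housekeeping genes, and markers of glia, neurons, oligodendrocytes, haematopoietic cells, and fibroblasts or epithelium. Members were counted by the adjusted p over all probe sets tested and by the adjusted p over the list alone. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 27 lists. Camera compares a list with the other genes, while fry asks whether its members move one way on balance. For a comparison of 1 array with 1 array, the list median was placed among 10000 random lists of the same size matched on mean signal, which describes those arrays only and treats genes as independent.

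The genes named in the text were chosen by a rule set before the data were examined. It took SYK, ZAP70 and the RXR genes. For PonA over both days it took the 12 higher and 12 lower genes with the largest smallest change among the 3 comparisons, all above the floor on both sides, plus up to 3 each way given as bounds. For each pair of arrays it took the 6 highest and 6 lowest genes above the floor on both sides with a mean signal above the array median, and for each list described the 2 to 4 members with the largest PonA effect or difference. Other members that passed the test, where a list had few of them, were named after their values were seen.

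The additive fit was tested on simulated data built from the 7934 probe sets of the real comparison, with 200 changed in each of 5 runs. It recovered 83.6% of probe sets changed 2-fold and 100% of those changed 4-fold, and 6.80% of its calls were false. The simulated noise was independent between probe sets and arrays, with no floor and no differences of day, ethanol or PonA-by-day. These rates therefore do not give the error rate of the real calls. Alternatives were quantile normalization, median centring, a floor at the 20th or 60th percentile, no floor but a pseudocount of 3.34, fold thresholds of 1.5 and 3, 1 probe set per gene, other terms and filters in the fit, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.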

Results

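Messenger RNA levels were profiled in U373 glioblastoma cells on 6 arrays, to follow the response of cells carrying an inducible syk construct to the inducer PonA. SYK is a tyrosine kinase best known from immune receptor signalling. 1 array each covered untransfected cells at day 1, transfected untreated cells at day 1 and day 2, transfected cells in ethanol, the solvent of the inducer, at day 1, and transfected cells in ethanol with 10 µM PonA at day 1 and day 2. No condition was repeated, no untransfected cells received PonA, and no ethanol array stood at day 2. The labels give 6 to 48 hours of PonA for the series as a whole, so the hours of exposure behind day 1 and day 2 are not known for each array. The arrays correlated with each other across probe sets at a Pearson r of 0.914 to 0.976 on the log2 scale. The 3' to 5' ratio of GAPDH lay between 0.939 and 1.04 on all 6 arrays. That of beta-actin lay between 0.960 and 0.987 at day 1 and was 1.21 in untreated and 1.20 in PonA-treated cells at day 2. The geometric mean signal of the spike-in probe sets was 157 on the untransfected array and between 271 and 501 on the transfected arrays.

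SYK, the transfected gene, was read by 3 probe sets that did not move together. The first SYK probe set gave 39.1 signal units with PonA at day 1 and 72.5 at day 2, and lay under the floor on every array without PonA, at 14.4 to 22.2 in transfected cells and at 1.74 in untransfected cells. Against the floor, the PonA signal was at least 1.54-fold that of ethanol and at least 1.49-fold that of untreated cells at day 1, and at least 3.12-fold that of untreated cells at day 2. In the additive limma fit its log2 PonA effect was 1.04 ± 0.26 (SE), which did not pass the threshold (adjusted p = 0.0803). The second SYK probe set gave 56.3 with PonA at day 1 against 64.1 with ethanol and 73.1 untreated, and 35.2 with PonA at day 2 against 22.0 untreated, and its log2 PonA effect was 0.10 ± 0.24 (SE, adjusted p = 0.877). The third SYK probe set stayed under the floor on all 6 arrays, with a highest signal of 6.50. ZAP70, the other kinase of the SYK family, gave a signal of at most 35.2, and its PonA effect was -0.11 ± 0.20 (SE, adjusted p = 0.835).

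The RXR genes encode the nuclear receptors that pair with the ecdysone receptor in inducible systems of this kind. The first of 2 RXRA probe sets gave between 640 and 867 signal units on the 5 transfected arrays, which is 6.73 to 9.12 times its signal in untransfected cells. The second RXRA probe set gave 375 in untransfected cells and 239 to 266 on the transfected arrays, a ratio of 0.637 to 0.710. Neither moved with PonA past the threshold, with log2 effects of -0.11 ± 0.20 (SE, adjusted p = 0.826) for the first and -0.02 ± 0.17 (SE, adjusted p = 0.976) for the second. The RXRB effect was -0.02 ± 0.16 (SE, adjusted p = 0.970) on its brighter probe set, and RXRG lay near the floor with an effect of -0.13 ± 0.21 (SE, adjusted p = 0.804).

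**Figure D1:**
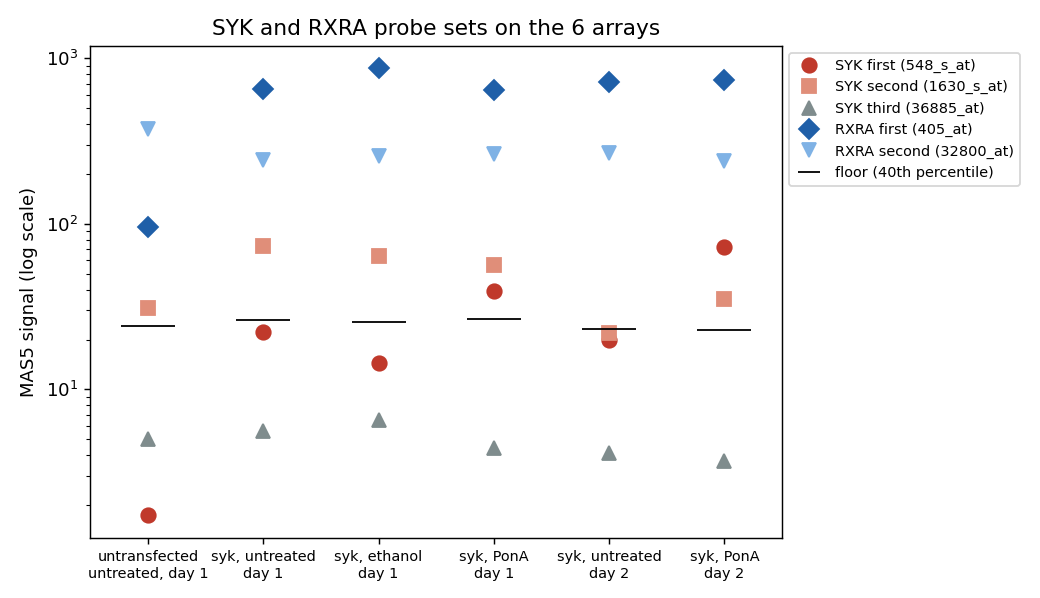
MAS5 signal (log axis) of 3 SYK and 2 RXRA probe sets on each of the 6 arrays; each point is 1 array and the black bars mark the floor of that array. The first SYK probe set exceeds the floor only on the PonA arrays, at 39.1 and 72.5, and the first RXRA probe set lies between 640 and 867 on the transfected arrays, at least 6.73 times its signal on the untransfected array.

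PonA treatment of the transfected cells went with lower levels of genes of mitosis and with higher levels of single genes such as SERPINA1, RGS4 and TNFRSF21, at both days. The named gene with the largest effect was SERPINA1, which encodes the secreted protease inhibitor alpha-1 antitrypsin. It rose from 55.7 with ethanol and 61.8 untreated to 1343 with PonA at day 1, and from 53.3 to 988 at day 2, a log2 effect of 4.39 ± 0.18 (SE) or 20.9-fold (adjusted p = 0.000461). RGS4, which shortens signalling through G proteins, rose 15.0-fold (log2 3.91 ± 0.31), and the death-domain receptor gene TNFRSF21 rose 12.5-fold (log2 3.64 ± 0.27), both with an adjusted p of 0.00395. At the other end PTTG1, which encodes the separase inhibitor securin, fell with a log2 effect of -3.24 ± 0.30, and UBE2C and CDC20, both parts of the machinery that marks mitotic proteins for destruction, with effects of -3.06 ± 0.25 and -2.95 ± 0.20, all with adjusted p of 0.00441 or less.

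Of 7934 probe sets tested, 402 passed the threshold, 214 higher and 188 lower with PonA, and they stand for 321 named genes. 323 of these calls exceeded 2-fold and 71 exceeded 4-fold, the smallest was 0.79 on the log2 scale, and the median SE over all tested probe sets was 0.19. By the rule of size, 203 probe sets differed at least 2-fold the same way in all 3 comparisons, 100 higher and 103 lower, and all 203 were among the 402. These p-values rest on 2 residual degrees of freedom that stand in for replicates, and they describe PonA given with its solvent in syk-carrying cells. The count of 402 moved with the arrays used: it was 111 without the PonA array of day 2, 134 without the untreated array of day 2, 202 without the PonA array of day 1 and 725 without the ethanol array.

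The other genes that the naming rule gave among the higher ones all passed the threshold with adjusted p between 0.00395 and 0.00537. SORBS2, which encodes an adaptor of the actin cytoskeleton, rose 9.52-fold, SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, 7.27-fold, the kinase gene DCLK1 7.16-fold and RCAN2, a regulator of calcineurin, 6.74-fold. RIN2, which encodes an exchange factor for endosomal Rab proteins, rose 5.56-fold, the laminin-binding integrin subunit gene ITGA7 4.99-fold, MAP2K3, which encodes an activator of p38 kinases, 4.70-fold, the cell-surface proteoglycan gene GPC4 4.56-fold and SCD, the desaturase of fatty acid synthesis, 4.26-fold. Genes under the floor on every control array of the fit had only bounds. The growth factor receptor gene KDR was at least 8.96-fold higher with PonA in each of the 3 comparisons (adjusted p = 0.00395), the growth factor gene VEGFC at least 5.99-fold (adjusted p = 0.00395), and the vitamin D receptor gene VDR at least 2.66-fold (adjusted p = 0.00652). For these 3 genes the ethanol difference in the limma fit was that of the floors, -0.05 on the log2 scale. Their p-values therefore leave out the spread of the control signals. The second KDR and VEGFC probe sets, also under the floor on every control array, were at least 0.99 and 1.59 higher in each comparison on the log2 scale. A second VDR probe set had a log2 effect of -0.02, and a second RIN2 probe set, under the floor in untreated cells at day 1, one of 1.15.

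The mitosis list moved as a block. Of its 34 tested genes 32 fell, none rose, and all 34 fell when p was adjusted over the list alone. The median log2 effect over these genes was -1.94, and the median difference was -1.69 against ethanol at day 1, -1.90 against untreated cells at day 1 and -2.22 against untreated cells at day 2. Among those that fell, the log2 effect was -2.84 ± 0.23 (SE) for KIF2C, a microtubule-depolymerising kinesin, -2.83 ± 0.20 for the mitotic kinase gene AURKA, and -2.79 ± 0.27 and -2.77 ± 0.21 for the cyclin genes CCNB1 and CCNB2. It was -2.57 ± 0.22 for the checkpoint gene BUB1B, -2.43 ± 0.23 for the spindle assembly gene TPX2 and -2.18 ± 0.18 for the kinesin gene KIF11. AURKA signal was 1108 with ethanol, 1185 untreated and 190 with PonA at day 1, and 1257 untreated and 142 with PonA at day 2. BUB1, CDC25C and KIF23 were under the floor on both PonA arrays and at least 3.36-fold, 3.46-fold and 3.13-fold lower there. The list differed from the other genes in camera at the preset correlation (adjusted p = 9.79e-48). With an estimated correlation, a test on 2 degrees of freedom that could hardly pass, the adjusted p was 0.684 (unadjusted p = 0.0694). Fry gave an adjusted p of 0.0787. LMNB1 and CITED1, named by the rule but outside this list, encode a nuclear lamin and a transcriptional co-regulator and also fell, with log2 effects of -2.74 ± 0.31 and -2.37 ± 0.17.

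Most DNA replication genes, 31 of 35, had a negative effect and 4 a positive one, with a median smaller in size than that of the mitosis list. Of 35 tested genes 8 fell and none rose, 18 fell when adjusted over the list alone, and the median log2 effect was -0.68. The log2 effect was -1.48 ± 0.19 (SE) for TYMS, the thymidylate synthase gene, -1.44 ± 0.23 for the flap endonuclease gene FEN1 and -1.34 ± 0.28 for the thymidine kinase gene TK1, which all fell. The ribonucleotide reductase gene RRM2 had an effect of -1.34 ± 0.30 (adjusted p = 0.0588). Camera gave an adjusted p of 1.55e-11 at the preset correlation and an adjusted p of 0.982 with an estimated correlation, and fry gave one of 0.232. Without the probe sets of the mitosis and DNA replication lists, a choice made after seeing the data, 315 probe sets passed the threshold, 193 higher and 122 lower.

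Among the immediate early and MAPK feedback genes, 8 of 27 rose, none fell, and 10 rose when adjusted over the list alone. The median log2 effect was 0.48. After SPRY2, the largest effects were those of DUSP6, a phosphatase of ERK kinases, at 2.39 ± 0.36 (SE, adjusted p = 0.0191), of the EGF receptor ligand gene HBEGF at 2.35 ± 0.24 (adjusted p = 0.00490) and of the MAP kinase phosphatase gene DUSP1 at 2.03 ± 0.32 (adjusted p = 0.0223). Part of the distance from untreated cells was also there with ethanol alone: at day 1 DUSP6 was at 1.16 and DUSP1 at 1.09 over untreated cells on the log2 scale, and with PonA they were at 1.54 and 1.51 over ethanol. The 8 that rose hold inhibitors of the pathway as well as a ligand. Camera gave an adjusted p of 1.21e-05 at the preset correlation and an adjusted p of 0.684 with an estimated correlation. The estimated correlation was -0.0046, under the preset one of 0.01. The larger p of that test therefore comes from its 2 degrees of freedom and not from correlated genes.

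Matrix and adhesion genes had a median log2 effect of 0.31 over 51 tested genes, of which 1 rose and 1 fell over all probe sets, and 9 rose and 2 fell when adjusted over the list alone. LAMB1, a laminin chain of basement membrane, rose by 1.84 ± 0.18 on the log2 scale (SE, adjusted p = 0.00465), and the protease gene MMP7 fell, with an effect of -1.89 ± 0.31 (SE, adjusted p = 0.0233). The collagen gene COL1A1 had an effect of 1.19 ± 0.30 (adjusted p = 0.0830). Camera gave an adjusted p of 8.52e-08 at the preset correlation and an adjusted p of 0.684 with an estimated correlation.

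Of 24 tested SYK signalling partners 1 fell, PRKCD, a protein kinase C gene, with a log2 effect of -0.84 ± 0.17 (SE, adjusted p = 0.0430), and none rose. LAT had an effect of -1.16 ± 0.37 (adjusted p = 0.146) and SOS1 of 0.98 ± 0.24 (adjusted p = 0.0731). The list median was 0.08, with 8 genes higher and 5 lower in all 3 comparisons, and camera gave an adjusted p of 0.239 at the preset correlation. In fry's mixed test, which counts moves in either direction, this list had the smallest adjusted p of the 27, at 0.00299, and 18 of the 27 passed. The mitosis list, with 32 of 34 genes called, had an adjusted p of 0.0336 in that test. Rank in the mixed test therefore does not follow the number of genes called. Of 23 NF-kB and inflammatory genes 1 rose, the interleukin receptor gene IL1R1, with log2 differences of 1.67, 1.68 and 1.27 in the 3 comparisons (adjusted p = 0.00827), and the list median was 0.00. Of 26 interferon-stimulated genes 1 fell, IFIT1, with an effect of -1.76 ± 0.21 (SE, adjusted p = 0.00787), the list median was -0.21, and camera gave an adjusted p of 0.0170 at the preset correlation and an adjusted p of 0.982 with an estimated correlation. The median difference of the interferon list was -0.18 over ethanol but 0.003 over untreated cells at day 1, and -0.17 over untreated cells at day 2. Adjusted over the list alone, the same numbers of SYK partners and inflammatory genes passed, and 2 interferon-stimulated genes fell.

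**Figure D2:**
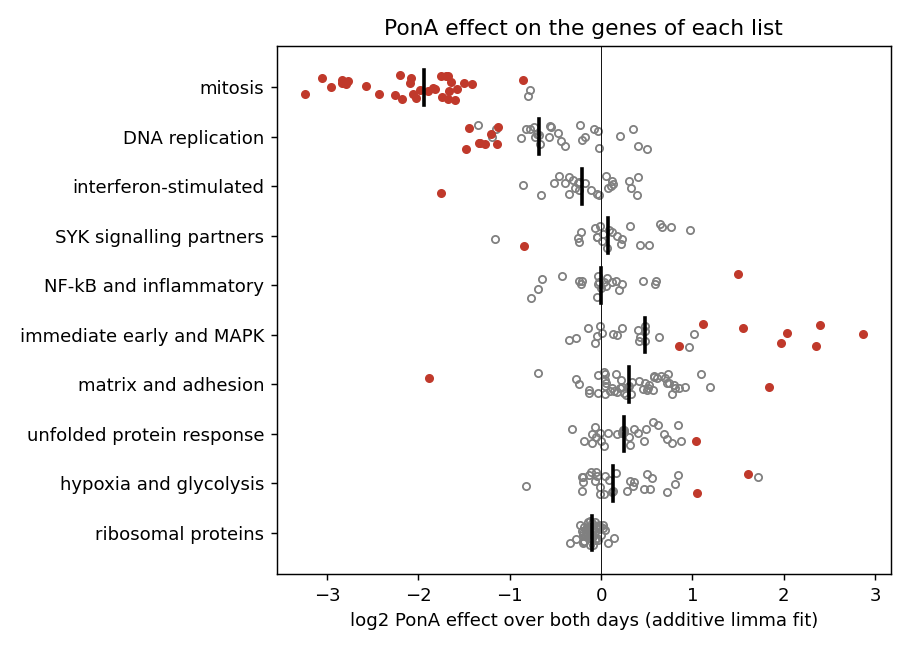
Log2 PonA effect over both days in the additive limma fit for the genes of 10 lists; each point is 1 gene, filled red where its adjusted p was under 0.05 and open otherwise, and the black bar is the list median. The mitosis genes lie at a median of -1.94 and the ribosomal protein genes at -0.10.

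The responses of the 2 days were compared through differences that share no array. PonA over ethanol at day 1 and PonA over untreated at day 2 correlated across 7787 probe sets with a Pearson r of 0.597 and a Spearman rho of 0.443, where genes are not independent replicates. Ethanol over untreated at day 1 and PonA over untreated at day 2, which also share no array, correlated with an r of 0.0975. At day 1, 258 probe sets were at least 2-fold higher and 192 lower with PonA than with ethanol, and 288 higher and 251 lower than in untreated cells. At day 2, 696 were at least 2-fold apart from untreated cells, 323 of them lower, where PonA and its solvent were not separated.

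Of the 34 mitosis genes, 30 lay further below the untreated array at day 2 than at day 1, and 33 of the 34 were lower with PonA in all 3 comparisons. Of 209 genes at least 2-fold apart from both controls at day 1, 193 went the same way at day 2 and 117 differed by more, which is 56.0%. SERPINA1 was 24.1-fold higher than with ethanol at day 1 and 18.5-fold higher than untreated at day 2, while RGS4 was 9.03-fold and 24.5-fold higher. EMP1, which encodes a membrane protein of epithelial cells, was 5.97-fold and 12.6-fold higher in these comparisons, and DUSP6 was 6.50-fold higher than untreated at day 1, of which a log2 difference of 1.16 was there with ethanol alone. AP1G2, an adaptor subunit of vesicle coats, was 10.7-fold lower at day 2, and the homeobox gene EVX1 was 5.28-fold higher than with ethanol at day 1, at 183 against 34.6, while untreated cells gave 122.

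Whether the response differed between the days was tested with a PonA-by-day term in limma, a fit chosen after seeing the data that leaves 1 residual degree of freedom, the difference of ethanol and untreated cells at day 1. It called 0 of 7934 probe sets, with 330 at an unadjusted p under 0.05. Among the 27 lists, 7 passed in camera at the preset correlation, and 0 passed with an estimated correlation (smallest unadjusted p 0.146) or in fry (smallest unadjusted p 0.00208). On 1 residual degree of freedom the estimated-correlation test could hardly pass any list, so its 0 decides nothing. The mitosis list had a median term of -0.54, further down at day 2, or -0.40 under quantile normalization (adjusted p = 4.14e-09 at the preset correlation and 0.737 with an estimated one). Day 2 had no ethanol array, so the term also holds whatever the solvent did at that day.

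**Figure D3:**
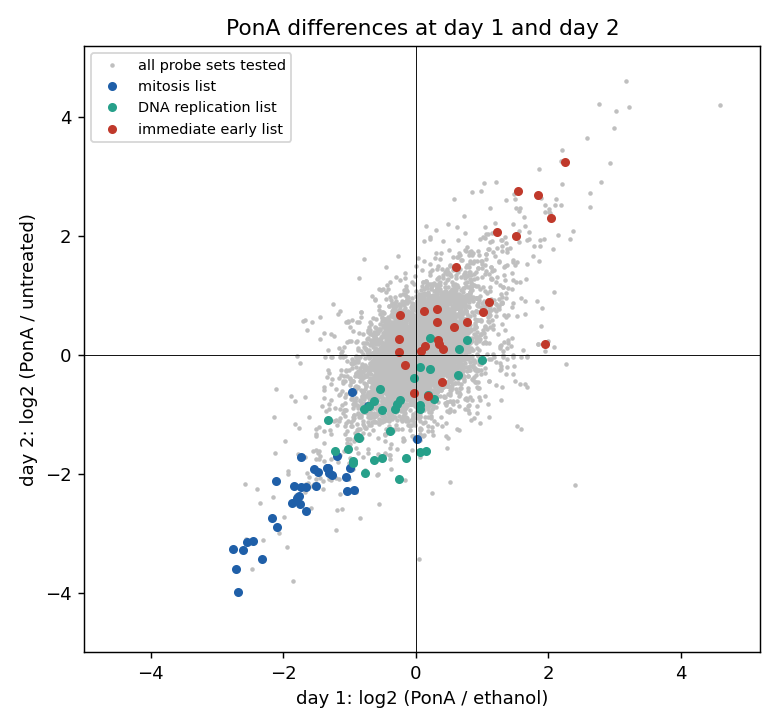
Log2 difference of PonA over ethanol at day 1 (horizontal axis) and of PonA over untreated at day 2 (vertical axis); each point is 1 probe set tested in the additive fit, with 3 gene lists in colour. The mitosis genes lie at the lower left, with medians of -1.69 and -2.22, and the correlation across 7787 probe sets is 0.597.

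Ethanol alone was set against no treatment at day 1, with 1 array each. The spike-in geometric mean was 271 on the ethanol array, against 474 on the untreated and 501 on the PonA array of that day. An effect of the solvent can therefore not be separated from a deviation of the ethanol array. With ethanol alone 83 probe sets were at least 2-fold higher and 92 lower, of 8015. APBA3 was 3.41-fold higher with ethanol at 124 against 36.3 signal units, the amino acid transporter gene SLC7A4 3.21-fold, the proteasome subunit gene PSMA7 3.16-fold, PCK2, the mitochondrial enzyme of gluconeogenesis, 3.15-fold, the transcription factor gene ETV5 2.58-fold and the water channel gene AQP8 2.56-fold. BAIAP3 was 3.87-fold lower, EVX1 3.54-fold, the lens protein gene BFSP2 2.97-fold, NDUFA9, a subunit of respiratory complex I, 2.79-fold, RAPGEF3, which encodes a cAMP-activated exchange factor, 2.65-fold and the cobalamin carrier gene TCN1 2.53-fold. APBA3, PSMA7 and RAPGEF3 differed the same way in untreated cells at day 2, at 102, 109 and 28.3 signal units. For them ethanol cannot be told apart from a deviation of the untreated day 1 array. The other genes named here were not among those named for time in untreated cells. EVX1 was at 34.6 with ethanol and 122.3 untreated, but at 182.5 on the PonA array of day 1, which also had ethanol. Unfolded protein and stress response genes had a median log2 difference of 0.21, at the 99.96th percentile of matched random lists, with DNA replication genes at -0.19 and the 0.94th percentile. Ribosomal protein genes were at -0.18 and housekeeping genes at -0.20 as deposited, at the 0.02th and 0.8th percentiles, and at -0.09 and -0.07 under quantile normalization. Mitosis genes were at -0.10, against the -1.69 of PonA over ethanol.

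Transfected and untransfected cells, both untreated at day 1, were compared to show what the construct did without inducer. They differed at least 2-fold in 460 of 8045 probe sets, 248 higher and 212 lower in transfected cells. Counting only probe sets that did so on all 3 transfected arrays without PonA, a rule added after seeing the data, left 72 higher and 74 lower of 7760. The glial filament gene GFAP was at 1533 in untransfected cells and between 103 and 221 on these 3 arrays, and the neurofilament gene NEFL at 458 against 23.6 to 26.5, so that they were 14.8-fold and 17.3-fold lower in transfected untreated cells at day 1. The signalling gene CHN1 was 5.15-fold lower, the secretory granule gene SCG2 4.58-fold and the microtubule-associated protein gene MAP1A 4.56-fold. The purine synthesis gene PFAS was 4.64-fold lower at day 1 but differed by 0.38 on the log2 scale in transfected cells of day 2. In the other direction IGFBP3, a carrier of insulin-like growth factors, was 7.12-fold higher, RXRA on its first probe set 6.87-fold, the transglutaminase gene TGM2 5.39-fold, the secreted protein gene MIA 5.29-fold, the further carrier gene IGFBP5 4.63-fold and the stress-response gene NUPR1 4.20-fold.

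By list, 9 lists lay under the 1st or above the 99th percentile of matched random lists at day 1, a cut chosen after seeing the data, and their medians are given over genes above the floor on at least 2 of the 4 arrays. DNA replication genes were lower in transfected cells, with a median log2 difference of -0.69 on the untreated, -0.87 on the ethanol and -0.33 on the day 2 untreated array, and LIG1 and MCM5 were at least 2-fold lower on all 3. Matrix and adhesion genes were higher, at 0.54, 0.53 and 0.28, with CDH2, COL6A3, LAMA4 and POSTN at least 2-fold higher on all 3. Hypoxia and glycolysis genes were at 0.27, 0.43 and 0.15, with MXI1, P4HA1 and PLOD2 at least 2-fold higher on all 3, and unfolded protein and stress response genes at 0.28, 0.59 and 0.08, with DDIT3 so. Glial markers were at -0.44, -0.39 and -0.03, with GFAP and the glutamate transporter gene SLC1A3 at least 2-fold lower on all 3. Sterol synthesis genes were at -0.41, -0.26 and -0.08, oxidative phosphorylation genes at -0.19, -0.19 and -0.03, alcohol and aldehyde metabolism genes at -0.27, -0.26 and -0.04, and metallothionein and oxidative stress genes at -0.23, 0.06 and 0.12. The spike-in signals of the single untransfected array were the lowest of the 6, at 157, and with 1 such array the construct cannot be separated from that culture or hybridisation.

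Time in culture was compared within treatments. In untreated transfected cells, 83 probe sets were at least 2-fold higher and 172 lower at day 2 than at day 1, but under quantile normalization the split was 125 and 112 and under median centring 105 and 138. The membrane glycoprotein gene GPNMB was 4.40-fold higher at day 2, PFAS 3.57-fold, PSMA7 3.01-fold, the bone transcription factor gene RUNX2 3.01-fold, RAB35 2.95-fold and APBA3 2.82-fold. MDFI, an inhibitor of myogenic factors, was 3.91-fold lower, the transaminase gene GPT 3.41-fold, RAPGEF3 3.30-fold, the calcium channel gene ORAI2 3.09-fold, the non-coding RNA gene MEG3 3.08-fold and the synuclein gene SNCG 2.95-fold. DNA replication genes had a median log2 difference of 0.44 and mitosis genes of 0.18, at the 100th and 99.5th percentiles of matched random lists, and matrix and adhesion genes of -0.18 at the 0.07th. Hypoxia and glycolysis genes were at -0.19, interferon-stimulated genes at 0.12 and alcohol and aldehyde metabolism genes at 0.36, also under the 1st or above the 99th percentile as deposited. Under quantile normalization they were at -0.07, 0.17 and 0.46 in that order. The untreated day 1 array also serves the ethanol and transfection comparisons, so their differences are not independent.

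With PonA, 70 probe sets were at least 2-fold higher and 163 lower at day 2 than at day 1, and 97 and 108 under quantile normalization. The collagen genes COL13A1 and COL8A1 were 3.72-fold and 3.04-fold higher at day 2, SCG2 3.41-fold, RUSC2 3.23-fold, the chitinase-like gene CHI3L2 3.10-fold and the transcript TPTEP1 3.04-fold. PSMA7 was 6.62-fold lower, AP1G2 5.76-fold, EVX1 4.79-fold, GTPBP1 4.27-fold, the fibroblast growth factor gene FGF4 3.61-fold and the neuronal RNA-binding protein gene ELAVL3 3.21-fold. Mitosis genes had a median log2 difference of -0.32 at the 0.03th percentile of matched random lists, which was -0.16 under quantile normalization. SYK signalling partners were at -0.32, hypoxia and glycolysis genes at -0.19, sterol synthesis genes at 0.28 and glial markers at 0.22, also under the 1st or above the 99th percentile as deposited. Under quantile normalization these medians were -0.19, -0.04, 0.28 and 0.25 in that order. Both time comparisons go with the beta-actin 3' to 5' ratio, which was 1.21 and 1.20 on the arrays of day 2 and at most 0.987 on those of day 1.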

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

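Of the tests in this part, that of SYK against noise near the floor was set before its result was seen, and those of the PonA-by-day term, array scaling, RNA degradation, the other choices of arrays, the receptor pair, probe placement and RXRA were chosen after it.

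SYK on its second probe set drew attention because the days went opposite ways: with PonA the log2 difference was 0.60 against untreated cells at day 2, and -0.19 against ethanol and -0.37 against untreated cells at day 1. The complement gene C9 was at least 2-fold apart in opposite directions, at -1.19 at day 2 against 1.53 and 1.07 at day 1, with signals of 27.1 to 78.1. The oligodendrocyte marker list had a median log2 difference of -0.31 at day 2 against 0.28 and 0.58 at day 1, over 4 tested genes, none of which passed the threshold. A PonA-by-day term in limma, with 1 residual degree of freedom, was 0.88 ± 0.40 (SE, adjusted p = 1.00) for this SYK probe set and -2.48 ± 0.46 (SE, adjusted p = 0.917) for C9, and neither passed.

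The same term flagged 7 lists, which passed in camera at the preset correlation. Its median over their probe sets was -0.54 for mitosis, -0.47 for DNA replication, -0.34 for apoptosis and survival, -0.63 for the oligodendrocyte markers, 0.88 for SYK and ZAP70, 0.38 for the unfolded protein and stress response and 0.13 for matrix and adhesion. The SYK and ZAP70 median covers 3 probe sets and is the value of the second SYK probe set given above. For DNA replication genes, the median log2 difference of day 2 over day 1 was 0.44 in untreated cells. With PonA it was -0.04, or 0.02 under quantile normalization, so the term of that list came mostly from the untreated arrays. All 7 lists kept their sign and passed under quantile normalization and median centring, and none passed with an estimated correlation (smallest unadjusted p among them 0.146) or in fry (smallest unadjusted p among them 0.0243). The miss with an estimated correlation decides nothing, because that test has 1 residual degree of freedom and could hardly pass any list.

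The pattern that invites most follow-up is the set of 402 probe sets called with PonA, with the mitosis genes lower. Array scaling is argued against as its whole source, since 342 of the 402 were also called after quantile normalization, and so is RNA degradation measured by the GAPDH and actin 3' to 5' ratios, of which the largest on a PonA array was 1.10 times that of a control array of the same day. There are 6 ways to take 1 array of each day as treated, too few for a share under 0.05; the real choice gave 402 limma calls and the highest of the others 0, with 94 to 827 at an unadjusted p under 0.05, though each of those others left PonA arrays on the wrong side. A direct action of PonA and its receptor pair without SYK cannot be told apart from an action of SYK, because no array holds PonA without the syk construct, and the median log2 effect of 0.10 over LXR and retinoid targets, whose members went both ways, decides nothing. An action of induced SYK on the cell cycle stays among the open explanations, untested.

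SYK itself exceeded the floor with PonA on its first probe set and on no array on the third. Noise near the floor is argued against, since 0.146% of the 4116 probe sets under the floor on the 4 arrays without PonA exceeded it on both PonA arrays by the margins of SYK, against 0.0243% and 0% for 2 other pairs of transfected arrays taken in place of the PonA arrays. Whether the second and the third read parts of the transcript outside the construct cannot be told apart from a failure of those probe sets, as no probe or construct sequence was used here, and the highest signal of the third was 6.50. The fitted SYK effect of 1.04 missed the adjusted threshold.

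The RXRA probe sets moved apart in transfected cells. RXRA message from a transfected plasmid is a candidate explanation for the first, whose smallest ratio over untransfected cells was 6.73 over the 5 transfected arrays. A rise of the cell's own RXRA gene is argued against, as long as the second reads its transcript, because its largest ratio was 0.710. The labels name no receptor plasmid, so the source of that signal stays a hypothesis.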

How the results depend on the processing

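The 3-array rule for transfection, the fit with a PonA-by-day term and its list tests, and the count without the mitosis and DNA replication lists were chosen after seeing the data. All other alternatives were set before, among them the estimated-correlation and fry tests of the additive fit. No gene or list past a threshold turned its direction, but the balance of some counts did. Under quantile normalization time untreated went from 83 higher and 172 lower to 125 and 112, ethanol from 83 and 92 to 100 and 84, and transfection from 248 and 212 to 221 and 244. Under median centring the PonA calls went from 214 and 188 to 202 and 205, and the lower side of PonA at day 2 from 323 of 696 to 348 of 690. Quantile normalization and median centring left every total within 1.5 times its reported value, though the lower count of time with PonA went from 163 to 108, and they moved the median of all genes by under 0.1. The 402 calls became 107 with the floor at the 20th percentile, 185 with ethanol as a term of its own, 725 without the ethanol array and paired by day (403 higher, 322 lower), 444 with a PonA-by-day term, averaged over the days, 625 with an intensity trend, 29 with no filter and 718 at an adjusted p of 0.1. Leaving out 1 array, with 1 residual degree of freedom, gave between 111 and 725 calls: 111 without PonA at day 2, 134 without untreated at day 2, 202 without PonA at day 1, 516 without untreated at day 1 and 725 without ethanol. Of the 30 genes named for PonA, 21 kept their direction but not the threshold with no filter, 3 with the floor at the 60th percentile (BUB1, CDC25C and KIF23) and 1 with the floor at the 20th (LMNB1). The correlation of the days was 0.415 with the floor at the 20th and 0.704 at the 60th percentile, over other numbers of probe sets. With the floor at the 20th percentile the 2-fold counts were 1064 for PonA over ethanol, 1337 for PonA at day 2, 861 for ethanol, 1329 for transfection, 1017 for time untreated and 773 for time with PonA; with the floor at the 60th they were 210, 402, 29, 167, 62 and 62 in that order. With a pseudocount and no floor they were 688 for PonA over ethanol, 414 for ethanol, 742 for transfection, 503 for time untreated and 395 for time with PonA, and the log2 SYK difference at day 1 was 1.25 in place of 0.62. With 1 probe set per gene the ethanol count was 116. At 1.5-fold the counts were 547 for the 3-comparison rule, then 1423, 1970, 1063, 1749, 1329 and 1250 in the order above, and at 3-fold 74, then 127, 256, 19, 86, 29 and 33. Transfection on all 3 arrays gave 146. Of the 27 lists 7 passed in camera, 0 with an estimated correlation (smallest unadjusted p 0.0303) and 0 in fry (smallest unadjusted p 0.00311), and leaving out 1 array gave between 4 (without untreated at day 2) and 7. The 0 with an estimated correlation was close to fixed by the 2 residual degrees of freedom of that test. The causes of these moves were not tested.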

Other observations

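The tests of stress, metabolic and marker lists were planned, and the test of leaky induction was chosen after the results were seen.

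Several lists outside the main pattern held single genes that changed with PonA, all in the additive limma fit. Of 19 TGF-beta targets 3 rose and none fell: the receptor gene TGFBR2 by 2.08 ± 0.21 (SE, log2, adjusted p = 0.00522), the inhibitory SMAD7 by 1.69 ± 0.21 (adjusted p = 0.00904) and the ligand gene TGFB1 by 1.58 ± 0.20 (adjusted p = 0.0106). The list median was -0.04. Of 15 glial markers 2 rose, SLC1A3 by 2.88 ± 0.26 (adjusted p = 0.00411) and PTPRZ1 by 1.12 ± 0.19 (adjusted p = 0.0261), while GFAP had an effect of 0.50 ± 0.23 (adjusted p = 0.299). Of 11 neuronal markers GAP43, a growth cone gene, fell, with an effect of -1.83 ± 0.20 (adjusted p = 0.00599) and none rose. Of 17 LXR and retinoid targets 2 rose, SCD and VDR, and 2 fell, DHRS3 with an effect of -1.23 ± 0.20 (adjusted p = 0.0238) and the retinoic acid receptor gene RARB of -1.21 ± 0.23 (adjusted p = 0.0394). Of 11 genes of alcohol and aldehyde metabolism ALDH1A3 rose by 1.32 ± 0.21 (adjusted p = 0.0221) and ALDH3B1 fell, with an effect of -1.84 ± 0.23 (adjusted p = 0.00893).

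Of 30 genes of the unfolded protein and stress response 1 rose, the chaperone gene HSPA5 by 1.04 ± 0.19 (adjusted p = 0.0309), with a list median of 0.26. Camera gave that list an adjusted p of 0.00280 at the preset correlation and an adjusted p of 0.982 with an estimated correlation. At day 1 the list median was 0.09 for PonA over ethanol, at the 90.6th percentile of matched random lists, and 0.21 for ethanol alone over untreated cells, at the 99.96th. Against untreated cells PonA was at 0.20 at day 1 and 0.45 at day 2, at the 99.62th and 100th percentiles, where PonA and its solvent were not separated. Of 32 hypoxia and glycolysis genes 2 rose, CA12 by 1.61 ± 0.23 (adjusted p = 0.0147) and NDRG1 by 1.05 ± 0.20 (adjusted p = 0.0355), with a list median of 0.13, and camera gave an adjusted p of 0.0163 at the preset correlation and an adjusted p of 0.982 with an estimated correlation. Of 15 sterol synthesis genes DHCR7 rose by 1.26 ± 0.20 (adjusted p = 0.0214), of 22 metallothionein and oxidative stress genes GCLC, of glutathione synthesis, rose by 1.30 ± 0.20 (adjusted p = 0.0207), and of 24 apoptosis and survival genes BIRC5, which also acts in mitosis, fell, with an effect of -1.60 ± 0.29 (adjusted p = 0.0309). No member passed the threshold among 15 p53 targets, 19 heat shock, 45 ribosomal protein, 48 oxidative phosphorylation and 15 housekeeping genes, or among 4 oligodendrocyte, 6 haematopoietic and 8 fibroblast or epithelial markers, and the medians of the ribosomal and oxidative phosphorylation lists were -0.10 and -0.07. Adjusted over the list alone, 4 TGF-beta targets, 3 glial markers, 5 hypoxia, 3 LXR or retinoid and 2 oxidative stress genes rose, while 3 LXR or retinoid, 4 oxidative stress and 1 hypoxia gene and the p53 target DDB2, at -0.87 ± 0.18, fell, and the counts of the other lists stayed as given. The sign of the gene median differed from that of a list test for SYK and ZAP70, heat shock, p53, sterol synthesis, TGF-beta, apoptosis, neuronal and fibroblast or epithelial lists, none of which passed camera or fry's test of 1 direction.

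Leaky induction before PonA is a hypothesis that was looked at on a difference of arrays not used to pick the genes. The 175 genes at least 2-fold apart the same way in PonA over ethanol at day 1 and PonA over untreated at day 2 were looked up in transfected over untransfected untreated cells. With signs turned to the PonA direction, their median log2 difference was 0.18, at the 100th percentile of 10000 random gene sets of the same size and signs. It was 0.16 over the 143 genes outside the mitosis and DNA replication lists. The median of 0.18 was small beside the day 1 PonA median of 1.47, and 60.6% of the genes went the PonA way. A gene under the floor on both arrays takes the difference of their floors, 0.12, which is also the median of the 94 genes higher with PonA. Such genes were kept among the 175 but not in the random sets. The 81 lower genes had a median of -0.25. The percentile and the share therefore cannot decide whether there was a weak response without inducer. Random gene sets also treat genes as independent, and other differences between the single untransfected array and the transfected cells could give the same values. SYK on its first probe set was under the floor in untransfected and in transfected untreated cells. Its second probe set gave 73.1 in untreated and 64.1 in ethanol-treated transfected cells at day 1, the first of them 2.35-fold the signal of untransfected cells, and 22.0, under the floor, in untreated transfected cells at day 2.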
